A study of Mus musculus with 83 samples.

How the data were processed

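Liver RNA of 83 mice was sequenced from strand-specific, oligo-dT selected libraries, per the labels' protocols. The authors deposited 1 table per mouse of whole-number read counts per gene, not normalised. Per the submitters' processing notes the tools were Trimmomatic, STAR 2.5, HTSeq 0.6.1p1 and DESeq2, with build GRCm38, without roles or settings. Whether the counting used the strand is not given in the sources used here, so genes that overlap on opposite strands are uncertain. Each deposited count table holds 54446 gene entries and 5 that name no gene, which were left out of library sizes and tests. These hold reads outside genes (2.13 to 2.98% of a table), reads in more than 1 gene (4.96 to 6.14%) and reads with more than 1 alignment (3.6 to 5.8%). The 10 most abundant genes held 14 to 19.9% of a library's gene reads. Symbols were taken from a table of gene names, where 53229 identifiers matched with their version and 54409 without it, and GRCm38 coordinates from a GENCODE annotation. A merged table with the same counts was not used.

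Groups came from the diet label of each mouse. The labels state housing of 3 mice per cage, an age of 15 to 18 weeks at the start, and randomised groups of 9 (chow), 13 (olive and rapeseed oil, sunflower oil, pork fat) and 14 (beef fat, milk fat) mice. In 8 libraries the code ends in R, whose meaning is not given.

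Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries scaled by TMM, and 1 quasi-likelihood model with robust dispersion was fitted to all libraries in 7 groups. The 19 comparisons are contrasts of that model, each with Benjamini-Hochberg adjustment and a threshold of 0.05. The mean of the 5 fats is a mean of 5 log2 fold changes, so it can differ from a ratio of mean levels. The SE of a log2 fold change is its size divided by the square root of its F statistic. Levels are CPM, as mean ± SD over mice; deeper libraries count low genes more precisely, and all libraries held at least 8519142 gene reads.

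The 32 gene lists, the comparisons and the rule for the genes named were fixed before the data were examined. The rule takes from each list up to 4 called members with the largest changes for the 5 fats against chow and for animal against plant fat, and up to 3 in the pairs within plant or animal fats and for HFD_TNO. It adds the 6 highest and 6 lowest called genes (4 and 4 in the pairs and HFD_TNO) with at least 5 CPM in a compared group and a named symbol, and a fixed set of index genes. Some genes are in more than 1 list. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the lists within a comparison; both treat mice as independent. The scripts were tested on simulated data with 200 changed genes and a slight shift of the respiratory chain list, whose calls were not counted as false. The 200 genes averaged above 1 CPM, and simulated mice of a prefix were no more alike than others. For animal against plant fat 36% of genes changed 1.25-fold, 80% of those changed 1.5-fold and 96% of those changed 2-fold were found. There were 9 false calls among 192 calls, with 15585 genes tested. For milk fat against chow 11 of 156 calls were false.

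Alternatives fixed in advance were DESeq2 size factors (RLE), no filter, the compared groups alone, counts summed over mice of the same prefix, voom with the prefix as a random block, leaving out the libraries coded R or using R as a covariate, and DESeq2 1.42.0. Not planned but chosen after seeing the data were leaving out 5 libraries that lie over 5 median absolute deviations from their group on a principal component, using a cell-marker score or a clock score as a covariate, and leaving out single mice. The cell-marker score is the mean z score of matrix, macrophage and endothelial genes minus that of hepatocyte markers. The clock score sums the levels of the clock genes, standardised over all mice and weighted by their first component after centring within diets. That component held 46.2% of the variance of the centred list. The consensus correlation of mice with the same prefix, over all genes, was 0.0287, but 12.7% of genes had a correlation above 0.2. Voom used the consensus for every gene, so it corrects little for those genes.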

Results

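Liver RNA was measured in 83 male Ldlr-/-.Leiden mice, a strain that lacks a working low-density lipoprotein receptor and becomes obese on high-fat feeding. The study asked how plant and animal fats in the diet differ in their effects. Mice stayed on chow (n = 8 libraries) or ate 1 of 5 high-fat diets of equal energy density for 28 weeks. These diets differed in the source of fat, and per the labels the vitamin mix of the milk fat diet also held 50% less vitamin A. The fats were olive and rapeseed oil mixed 20 to 80 (n = 13), sunflower oil (n = 10), beef fat (n = 14), milk fat (n = 14) and pork fat (n = 13), each giving 45% of the energy. A further high-fat group, named HFD_TNO in the labels (n = 11), has a diet that the sources used here do not describe. Each mouse gave 1 library, with 8519142 to 32809104 reads counted to genes (median 17006713), and 15790 genes had enough reads to be tested. Mouse numbers share a prefix in sets of up to 3 mice, 35 prefixes in all, each within 1 diet. A shared prefix is probably a shared cage, which the labels do not state.

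On the first principal component of the 2000 most variable genes, which held 17.8% of their variance, chow livers averaged -52.7 ± 16.5 (SD, n = 8). The means were -11.7 ± 19.7 on olive and rapeseed oil (n = 13), 1.9 ± 11.6 on sunflower oil (n = 10) and 8.5 ± 15.2 on pork fat (n = 13). They were 16.7 ± 6.9 on beef fat (n = 14) and 18.7 ± 9.2 on milk fat (n = 14). HFD_TNO livers averaged -4.5 ± 14.8 (n = 11).

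The comparison of the 5 fats with chow asked how livers on the high-fat diets differed from livers on chow. No fat share or energy density is recorded here for chow, so its other differences from these diets cannot be separated from fat. Genes of lipid storage rose. Cidec, a protein that enlarges lipid droplets (GRCm38 chromosome 6, 113424634 to 113435760), averaged 4.38 ± 3.42 CPM (library-scaled counts, SD, n = 8) on chow and 144 ± 31.9 CPM on milk fat (n = 14). Its log2 fold change on the mean of the 5 fats was 4.71 (SE 0.33, edgeR adjusted p = 1.03e-20). Its relative Cidea rose by 6.12 (SE 0.71), the apolipoprotein gene Apoa4 by 3.77 (SE 0.31), the acyltransferase Mogat1 by 3.60 (SE 0.29), the fatty acid transporter Cd36 by 2.64 (SE 0.16) and the droplet coat gene Plin4 by 1.87 (SE 0.22). Of the 27 lipid droplet and triglyceride storage genes, 17 were higher and 2 lower over all genes, and 18 were higher and 2 lower adjusted over the list alone. Their median log2 fold change was 0.49 (camera adjusted p = 2.09e-10, and adjusted p = 0.018 with an estimated correlation). In all, 6739 of 15790 genes passed an adjusted p of 0.05, with 3431 higher and 3308 lower, and 1857 of them changed at least 2-fold.

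Genes with sex-biased expression in mouse liver changed in these male mice. The steroid dehydrogenase Hsd3b5 (chromosome 3, 98618634 to 98630252) averaged 199 ± 64.8 CPM on chow (n = 8) and 0.124 ± 0.195 CPM on milk fat (n = 14), with a log2 fold change of -8.59 (SE 0.48, adjusted p = 8.53e-26) on the mean of the 5 fats. The fall was smaller in some livers. On olive and rapeseed oil replicates 3 and 8 were at 5.423 and 3.19 log2 CPM, against 6.741 or more on chow. The organic anion transporter Slco1a1 (-5.56, SE 0.44) and the glucuronosyltransferase Ugt2b38 (-5.97, SE 0.43) fell too. Of the 24 measured male-biased genes, 24 were lower, both over all genes and adjusted over the list alone. Camera gave an adjusted p = 2.26e-27 at a median log2 fold change of -2.39, and adjusted p = 0.018 with an estimated correlation. Among 23 female-biased genes the cytochrome P450 gene Cyp2b9 averaged 0.971 ± 2.23 CPM on chow and 203 ± 54.2 CPM on sunflower oil (n = 10), with a log2 fold change of 7.46 (SE 0.48, adjusted p = 1.76e-22), and the oxidase Hao2 rose by 5.97 (SE 0.59). Of that list, 13 were higher and 1 lower, both over all genes and adjusted over the list alone. At a median log2 fold change of 1.18, camera gave adjusted p = 2.03e-10, and adjusted p = 0.0268 with an estimated correlation. Without chow replicate 3, the chow liver with the highest Cyp2b9 and Hao2, these changes were 9.86 (SE 0.52) and 8.69 (SE 0.77). Cyp2b9, Cyp2b13 (8.59, SE 1.01) and the major urinary protein gene Mup7 (-9.18, SE 0.54) have near-identical copies, so how reads were divided within their families is uncertain. With the cell-marker score described next as a covariate, 11 male-biased genes were lower (median -1.31), and Hsd3b5 was at -2.1 (adjusted p = 0.257). Slco1a1 (-1.17, adjusted p = 0.535) and Mup7 (-2.90, adjusted p = 0.328) lost their calls there too. The female-biased list moved further from chow with that score, with 14 genes higher at a median of 2.73.

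Markers of matrix and macrophages rose on the 5 fats, and hepatocyte markers fell. Collagen Col1a1 (chromosome 11, 94936224 to 94953042) averaged 22.5 ± 13.7 CPM on chow (n = 8) and 255 ± 86.1 CPM on milk fat (n = 14), a log2 fold change of 3.05 (SE 0.35, adjusted p = 1.24e-11) on the mean of the 5 fats. The protease inhibitor Timp1 (4.28, SE 0.61) and the collagen cross-linking enzyme Lox (3.17, SE 0.53) rose with it. Col1a1 was not above the chow range in every liver. Replicates 3, 9 and 6 on olive and rapeseed oil were at 4.519, 5.572 and 5.595 log2 CPM, against up to 5.6 on chow. Of the 40 stellate cell and matrix genes, 38 were higher and 1 lower over all genes, and 39 were higher and 1 lower adjusted over the list alone. The median was 1.52 on the log2 scale (camera adjusted p = 5e-24, and adjusted p = 0.031 with an estimated correlation). Of the macrophage genes, Gpnmb rose by 5.15 (SE 0.63), the elastase Mmp12 by 4.14 (SE 0.46) and the lipid receptor Trem2 by 3.45 (SE 0.38). Of the 29 on that list, 26 were higher and 1 lower, both over all genes and adjusted over the list alone. Across the list the median log2 fold change was 1.49 (camera adjusted p = 3.85e-18, and adjusted p = 0.031 with an estimated correlation). Of the 18 hepatocyte markers, 17 were lower, both over all genes and adjusted over the list alone. By camera they had adjusted p = 3.3e-16 at a median log2 fold change of -0.77, and adjusted p = 0.0235 with an estimated correlation. Among them the amino acid enzymes Tat (-1.70, SE 0.14), Cps1 (-1.38, SE 0.10) and Hal (-1.19, SE 0.12) fell. A score of matrix, macrophage and endothelial markers minus hepatocyte markers averaged -3.32 ± 0.48 on chow (n = 8) and -0.63 to 1.11 on the 5 fats. With this score as a covariate, chosen after the data were seen, 960 genes passed in place of 6739. Chow livers lie apart from the rest on the score, so this fit cannot separate diet from cell makeup well, and for the lists that make up the score it tests nothing.

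The interferon-induced genes Ifi44 (2.72, SE 0.45) and Ifit2 (1.94, SE 0.26) rose. Of the 28 interferon response genes, 23 were higher over all genes, and 24 were higher adjusted over the list alone. As a list they had a median log2 fold change of 1.09 (camera adjusted p = 2.16e-08, but adjusted p = 0.258 with an estimated correlation). The monocyte attractant Ccl2 rose by 4.03 (SE 0.50). Of the 26 chemokines and cytokines, 16 were higher and 2 lower, both over all genes and adjusted over the list alone. Their median log2 fold change was 1.19 (camera adjusted p = 1.13e-05, but adjusted p = 0.083 with an estimated correlation). Cyclin Ccnb1 (2.24, SE 0.43) and the mitotic kinase Plk1 (2.18, SE 0.39) rose. Of the 28 cell cycle genes, 22 were higher and 1 lower, both over all genes and adjusted over the list alone. Camera gave an adjusted p = 1.6e-08 at a median log2 fold change of 1.45, and adjusted p = 0.0443 with an estimated correlation. In the fit with the cell-marker score Ccnb1 (0.70, adjusted p = 0.638), Plk1 (0.91, adjusted p = 0.425), Ifi44 (0.91, adjusted p = 0.448), Ifit2 (0.27, adjusted p = 0.759) and Ccl2 (1.07, adjusted p = 0.222) lost their calls. Of the 25 lymphocyte markers, 1 was higher and 1 lower over all genes, and 1 was higher adjusted over the list alone. At a median log2 fold change of 0.32, camera gave adjusted p = 0.638.

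Bile acid, sterol and fatty acid genes went in different directions. Cyp7b1, an oxysterol hydroxylase, fell by 3.26 on the log2 scale (SE 0.18), Cyp2c70, which makes muricholic acids, fell by 2.03 (SE 0.13), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.31 (SE 0.29). Of the 15 bile acid synthesis genes, 1 was higher and 11 lower, both over all genes and adjusted over the list alone. The median was -0.46 on the log2 scale (camera adjusted p = 2.7e-06, but adjusted p = 0.0632 with an estimated correlation). With the cell-marker score 2 of them stayed lower and the median turned to 0.11, while Cyp7a1 was at -1.24 (adjusted p = 0.221). Of the sterol enzymes, Tm7sf2 was at -1.20, SE 0.13, and Cyp51 at -0.97, SE 0.14. Both lost their calls with the score (-0.16, adjusted p = 0.795, and -0.53, adjusted p = 0.29). Of the 24 cholesterol synthesis genes, 1 was higher and 13 lower over all genes, and 1 was higher and 15 lower adjusted over the list alone. Across the list the median log2 fold change was -0.36 (camera adjusted p = 0.000334, but adjusted p = 0.504 with an estimated correlation). The pantetheinase Vnn1 (2.23, SE 0.17), the hormone Fgf21 (2.09, SE 0.30) and the thioesterase Acot2 (2.08, SE 0.23) rose, as members of a list of 45 PPARalpha and fatty acid oxidation genes. Of these, 26 were higher and 6 lower over all genes, and 26 were higher and 7 lower adjusted over the list alone. By camera they had adjusted p = 1e-06 at a median log2 fold change of 0.24, but adjusted p = 0.261 with an estimated correlation. Fatty acid synthase, Fasn, rose by 1.22 (SE 0.19), and the desaturase Scd1 was at 0.30, SE 0.19, adjusted p = 0.206. Of the 21 de novo lipogenesis genes, 12 were higher and 4 lower over all genes, and 13 were higher and 4 lower adjusted over the list alone. As a list they had a median log2 fold change of 0.45 (camera adjusted p = 0.0302, but adjusted p = 0.591 with an estimated correlation). Ldlr, disrupted in all of the mice, was at -0.11, SE 0.08, adjusted p = 0.294, which checks no label because no mouse with an intact gene was measured. It turned to 0.36, adjusted p = 0.0889 with the cell-marker score.

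Each diet was also compared with chow alone. The number of genes that passed was 4046 for olive and rapeseed oil, 4900 for sunflower oil, 5767 for pork fat, 6588 for beef fat, 6804 for milk fat and 4931 for HFD_TNO. Higher than chow in all 5 fat diets were 1759 genes, and 1374 were lower; 2 of 8182 genes called in any diet were called in opposite directions by different diets. These comparisons share the 8 chow libraries, which can raise their overlap. Unchanged groups simulated with the same library sizes gave 0 genes called by edgeR in all 5 in each of 10 simulations. Such groups hold no true changes, so this count does not measure how far the shared libraries raise the overlap. Independent lists of these sizes would share 3.5 higher and 1.8 lower genes, but lists with shared chow livers are not independent. With the chow livers divided between the plant oils and the animal fats, in either of 2 ways, at least 948 genes were higher and at least 622 lower in all 5. The median log2 fold change of the matrix list against chow was 0.94 on olive and rapeseed oil, 1.29 on sunflower oil, 1.48 on pork fat, 1.79 on beef fat and 1.80 on milk fat. For the male-biased list the medians in that order were -1.76, -2.18, -2.46, -2.75 and -3.19.

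**Figure D1:**
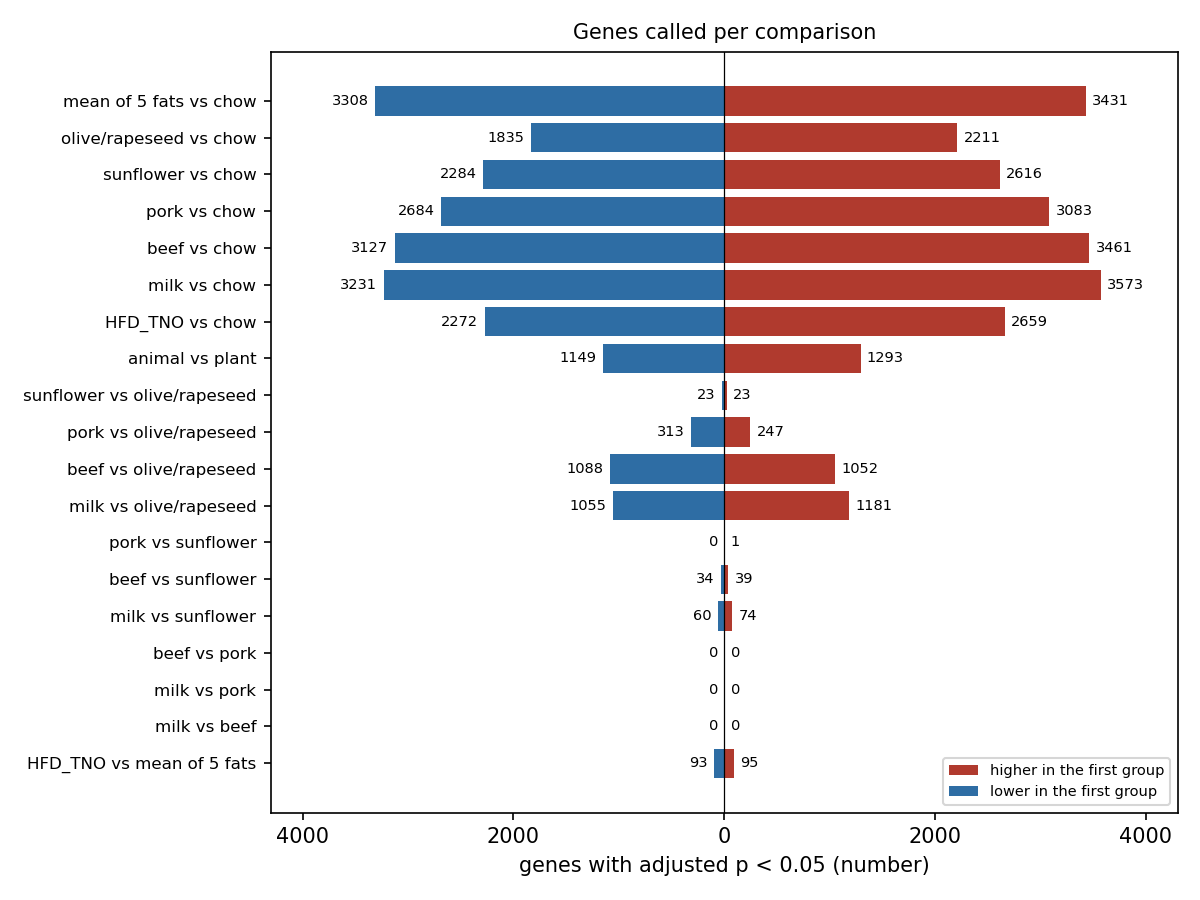
Number of genes with an edgeR adjusted p under 0.05 in each of the 19 comparisons, split into genes higher and genes lower in the first-named group. Single diets against chow reach 4046 to 6804 genes, animal against plant fat 2442, and the pairs of animal fats 0.

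**Figure D2:**
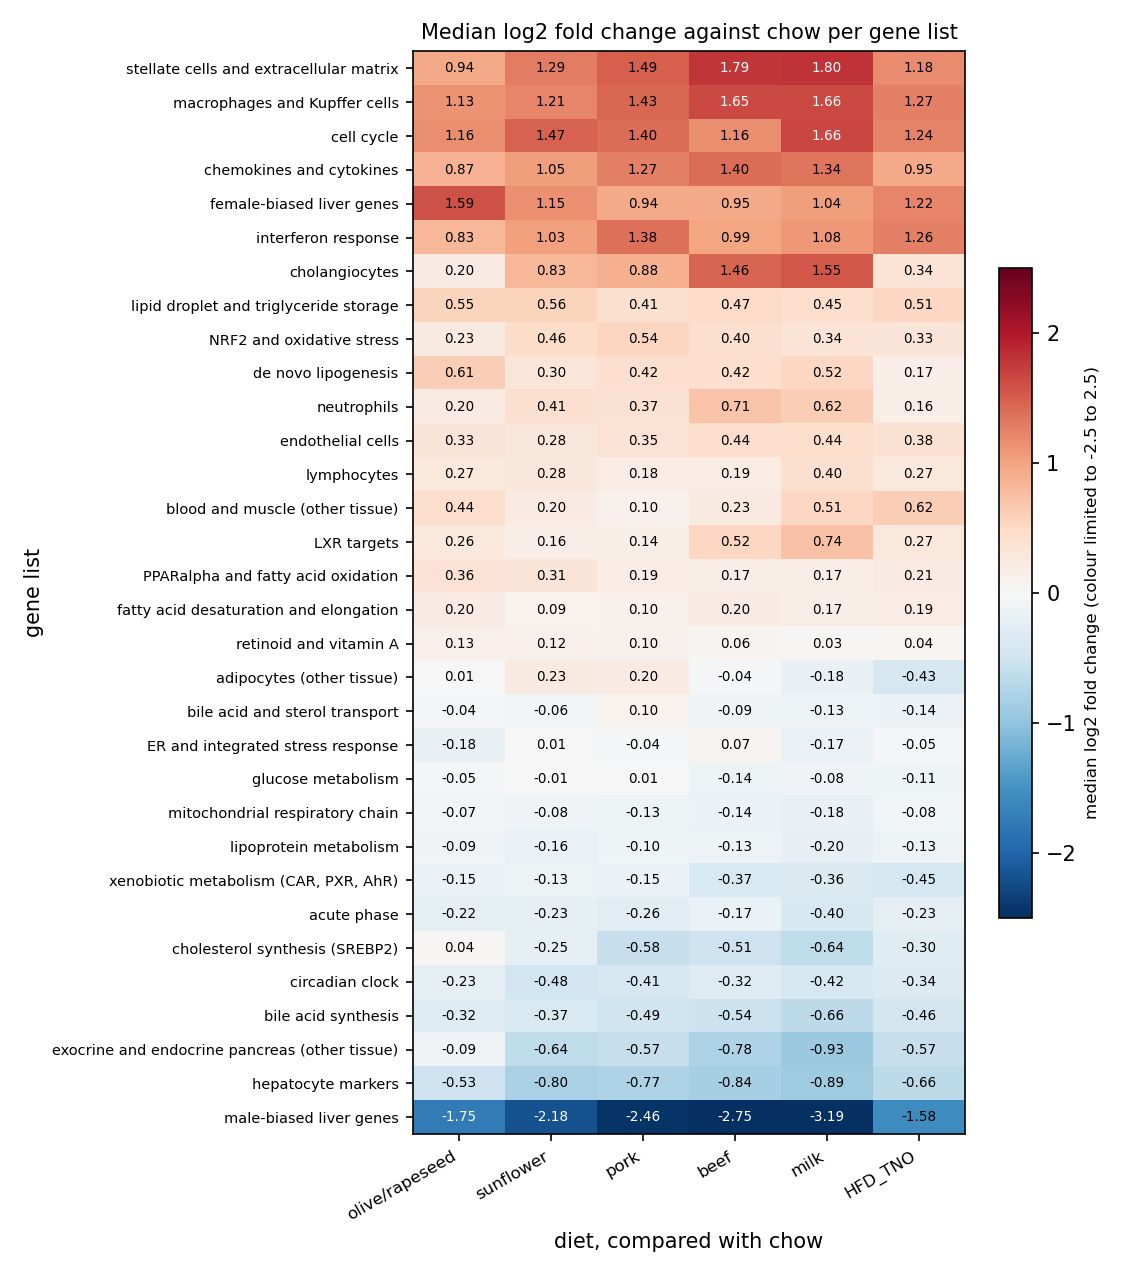
Median log2 fold change against chow of the 32 gene lists on each high-fat diet, with the value printed in each cell. The matrix list runs from 0.94 on olive and rapeseed oil to 1.80 on milk fat, and the male-biased list from -1.76 to -3.19.

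Animal fats (pork, beef and milk) were next compared with plant oils (olive and rapeseed, sunflower). Cholesterol synthesis genes were lower with animal fats. Squalene epoxidase, Sqle (chromosome 15, 59315077 to 59331192), averaged 91.2 ± 32.6 CPM on olive and rapeseed oil (n = 13), 77.6 ± 18.2 on sunflower oil (n = 10), 45.7 ± 24.2 on pork fat (n = 13), 51.5 ± 16 on beef fat (n = 14) and 42.7 ± 14.9 on milk fat (n = 14), against 99.1 ± 26.5 on chow. The log2 fold change of Sqle was -0.86 (SE 0.15, adjusted p = 7.41e-05). The sterol enzymes Cyp51 (-0.79, SE 0.11), Idi1 (-0.78, SE 0.13) and Nsdhl (-0.75, SE 0.10) were lower too, and so was Hmgcr, which sets the rate of the pathway (-0.29, SE 0.10, adjusted p = 0.0386). Of the 24 genes of the list, 22 were lower over all genes, and 24 were lower adjusted over the list alone. Their median log2 fold change was -0.51 (camera adjusted p = 2.69e-28, and adjusted p = 0.046 with an estimated correlation). Altogether 2442 genes passed, 1293 higher and 1149 lower with animal fats, of which 146 changed at least 2-fold. With counts summed over mice of the same prefix 1481 genes passed, and with the cell-marker score as a covariate 39 did, with 8 sterol genes lower (median -0.41). Hmgcr lost its call at about the same fold with the prefix sums (-0.31, adjusted p = 0.109), without a filter on low counts (-0.29, adjusted p = 0.0517) and with the score (-0.31, adjusted p = 0.364).

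Some fatty acid oxidation, bile acid and male-biased genes were lower with animal fats, though none of these lists passed with an estimated correlation. The fatty acid binding protein Fabp1 (-0.52, SE 0.10), the isomerase Eci2 (-0.40, SE 0.05) and the thioesterase Acot3 (-0.89, SE 0.32, adjusted p = 0.0483) fell. Of the 45 PPARalpha and fatty acid oxidation genes, 2 were higher and 28 lower over all genes, and 2 were higher and 35 lower adjusted over the list alone. Camera gave an adjusted p = 1.47e-16 at a median log2 fold change of -0.19, but adjusted p = 0.134 with an estimated correlation. With counts summed over prefixes 15 of them were lower, and with the cell-marker score 1. Acot3 kept no call under 6 of the alternatives (adjusted p = 0.0539 to 0.833, at -0.98 to -0.36), and Slco1a1 none with voom (-1.85, adjusted p = 0.148) or the score (-0.89, adjusted p = 0.542). The sterol hydroxylase Cyp8b1 (-0.59, SE 0.11) and Cyp7b1 (-0.53, SE 0.16) fell among 15 bile acid synthesis genes. Of these, 7 were lower over all genes, and 8 were lower adjusted over the list alone. At a median log2 fold change of -0.12, camera gave adjusted p = 0.000132, but adjusted p = 0.178 with an estimated correlation. With the score Fabp1, Cyp8b1 and Cyp7b1 lost their calls at -0.23, -0.31 and -0.15 (adjusted p = 0.379, 0.288 and 0.872). Slco1a1 (-2.31, SE 0.45) and the urinary protein gene Mup21 (-1.36, SE 0.19) fell among 24 male-biased genes. Of these, 12 were lower over all genes, and 15 were lower adjusted over the list alone. The median was -0.50 on the log2 scale (camera adjusted p = 2.07e-09, but adjusted p = 0.178 with an estimated correlation). Of the 18 hepatocyte markers, 10 were lower, both over all genes and adjusted over the list alone. Across the list the median log2 fold change was -0.17 (camera adjusted p = 6.46e-08, but adjusted p = 0.178 with an estimated correlation). Albumin, Alb, was at -0.31, SE 0.06.

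Many matrix, macrophage and bile duct markers were higher with animal fats, though none of these lists passed with an estimated correlation. The proteoglycan Lum (0.87, SE 0.18), the gelatinase Mmp2 (0.82, SE 0.15) and Col1a1 (0.77, SE 0.19) rose. Of the 40 matrix genes, 29 were higher and 1 lower over all genes, and 32 were higher and 1 lower adjusted over the list alone. By camera they had adjusted p = 2.07e-16 at a median log2 fold change of 0.46, but adjusted p = 0.178 with an estimated correlation. Of the macrophage genes, Ms4a7 (1.08, SE 0.21), Adgre1 (0.64, SE 0.16) and Trem2 (0.63, SE 0.19) rose. Of the 29 on that list, 17 were higher over all genes, and 22 were higher and 1 lower adjusted over the list alone. As a list they had a median log2 fold change of 0.37 (camera adjusted p = 7.35e-09, but adjusted p = 0.178 with an estimated correlation). Of these 8 were higher with counts summed over prefixes, 10 without the libraries whose code ends in R and 11 without 5 libraries that stand apart from their groups. Trem2 lost its call at a similar fold with the prefix sums (0.60, adjusted p = 0.0859) and without those 5 libraries (0.54, adjusted p = 0.0512). The transcription factor Ehf (1.16, SE 0.24), Bicc1 (0.78, SE 0.13) and the adhesion molecule Epcam (0.74, SE 0.17) rose. Of the 14 cholangiocyte genes, 8 were higher over all genes, and 11 were higher adjusted over the list alone. Their median log2 fold change was 0.72 (camera adjusted p = 2.03e-08, but adjusted p = 0.0814 with an estimated correlation). When the cell-marker score, which is not built from this list, was a covariate, edgeR called 0 of them higher (median 0.27). The sterol exporters Abcg1 (0.67, SE 0.10) and Abca1 (0.31, SE 0.05) and the desaturase Scd1 (0.43, SE 0.13) rose among 13 LXR targets. Of these, 5 were higher and 1 lower over all genes, and 5 were higher and 2 lower adjusted over the list alone. Camera gave an adjusted p = 0.0328 at a median log2 fold change of 0.18, but adjusted p = 0.178 with an estimated correlation. Scd1 lost its call with the prefix sums (0.44, adjusted p = 0.094) and with the score (0.43, adjusted p = 0.274). The cell-marker score averaged -0.63 ± 0.95 on olive and rapeseed oil (n = 13), 0.25 ± 0.46 on sunflower oil (n = 10), 0.31 ± 0.95 on pork fat (n = 13), 0.89 ± 0.50 on beef fat (n = 14) and 1.11 ± 0.59 on milk fat (n = 14).

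The smallest adjusted p belonged to Adam11, a protein of the metalloprotease family (chromosome 11, 102761439 to 102780262), at 1.5 (SE 0.15, adjusted p = 5.82e-12). Adam11 averaged 40.1 ± 19.8 CPM on chow (n = 8), 16.8 ± 6.27 on olive and rapeseed oil, 14.3 ± 4.28 on sunflower oil, 35.9 ± 12.9 on pork fat, 43.4 ± 13.8 on beef fat and 54.7 ± 12.9 on milk fat. Against chow it was lower on olive and rapeseed oil (-1.25, SE 0.23, adjusted p = 1.4e-05) and sunflower oil (-1.49, SE 0.25, adjusted p = 1.54e-06), and was at -0.16, SE 0.23, adjusted p = 0.632 on pork fat, 0.11, SE 0.23, adjusted p = 0.729 on beef fat and 0.45, SE 0.23, adjusted p = 0.111 on milk fat. Gipc2 (1.64, SE 0.32) and the neurotrophin receptor Ntrk2 (1.21, SE 0.21) were also higher with animal fats. With the cell-marker score as a covariate Adam11 kept its call (1.28) and Gipc2 lost it (0.65, adjusted p = 0.465).

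**Figure D3:**
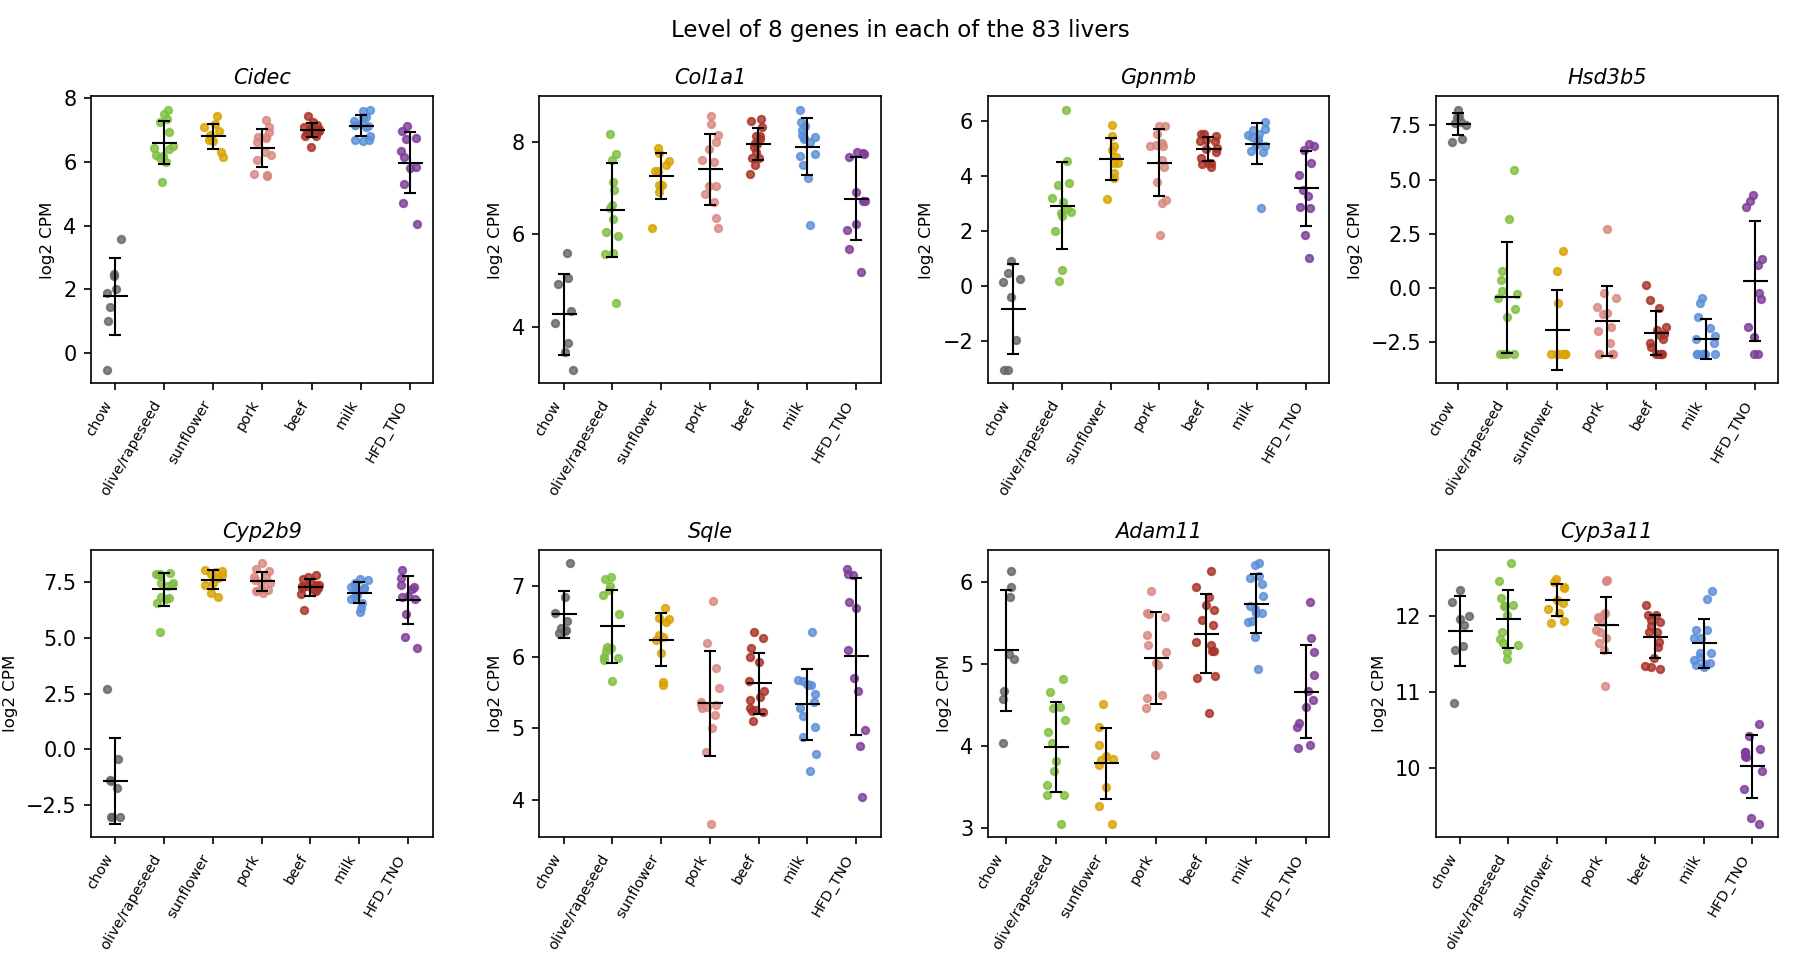
Log2 CPM of 8 genes in each of the 83 livers by diet group, 1 point per liver, with group mean and SD. Sqle is lower on the animal fats than on the plant oils (log2 fold change -0.86), Adam11 is higher (1.5), and Cyp3a11 is lower in HFD_TNO than on the mean of the 5 fats (-1.84).

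Within the plant oils, a few lipogenic genes were lower on sunflower oil than on olive and rapeseed oil, though not in fits that respect mouse-number prefixes. Thrsp, a regulator of lipogenesis, was at -1.14, SE 0.23, adjusted p = 0.0169, the phosphatidate phosphatase Lpin1 at -1.23, SE 0.30, adjusted p = 0.0442 and Fasn at -0.69, SE 0.19, adjusted p = 0.0895, which DESeq2 called (-0.69, adjusted p = 0.0424). Of the 21 de novo lipogenesis genes, 2 were lower over all genes, and 13 were lower adjusted over the list alone. At a median log2 fold change of -0.44, camera gave adjusted p = 6.46e-13, and adjusted p = 0.0264 with an estimated correlation. The clock gene Npas2 was higher on sunflower oil (2.17, SE 0.50, adjusted p = 0.0305). Of the 20 circadian clock genes, 1 was higher over all genes, and 2 were higher and 8 lower adjusted over the list alone. The median was -0.32 on the log2 scale (camera adjusted p = 1.07e-05, and adjusted p = 0.0264 with an estimated correlation). The choline kinase Chka rose (0.84, SE 0.20) and the reductase Por fell (-0.77, SE 0.18), while Hnf1b rose (0.41, SE 0.09) among 14 cholangiocyte genes. Of these, 1 was higher over all genes, and 10 were higher adjusted over the list alone. Across the list the median log2 fold change was 0.64 (camera adjusted p = 6.23e-10, and adjusted p = 0.0264 with an estimated correlation). Of the 18 hepatocyte markers, 1 was lower over all genes, and 10 were lower adjusted over the list alone. By camera they had adjusted p = 5.1e-10 at a median log2 fold change of -0.22, but adjusted p = 0.0987 with an estimated correlation. In all 46 genes passed, 23 higher and 23 lower. The camera tests treat mice as independent, although mice of a prefix had similar clock scores, so the list p values here are uncertain. Of the genes named, Npas2, Chka, Lpin1, Thrsp, Por and Hnf1b lost their calls in the fits with prefix sums, without libraries coded R, with these groups alone, with voom and with either score. Apart from the clock score, Npas2 stayed at 2.12 to 2.36 and Chka at 0.87 with prefix sums and 0.85 with the cell-marker score. The clock score, which contains Npas2, took Npas2 to 0.49, Chka to 0.17, Thrsp to -0.65 and Por to -0.44. With edgeR, 0 passed with counts summed over prefixes (1369 at an unadjusted p under 0.05) and 2 without the libraries coded R. These groups fitted alone gave 13, 3 higher and 10 lower. Without a filter on low counts edgeR called 231, 173 higher and 58 lower. DESeq2 called 112, 53 higher and 59 lower, and voom with the prefix as a random block 1.

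A score over 20 clock genes, high where Npas2 is high, averaged -2.45 ± 1.37 on olive and rapeseed oil (n = 13) and 2.11 ± 3.84 on sunflower oil (n = 10). The 3 mice of 1 sunflower prefix had scores of -3.07 to -2.70, and the mice of the other sunflower prefixes 1.59 to 6.89. With this score as a covariate 0 genes passed between these oils with edgeR, and 1510 at an unadjusted p under 0.05.

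**Figure D4:**
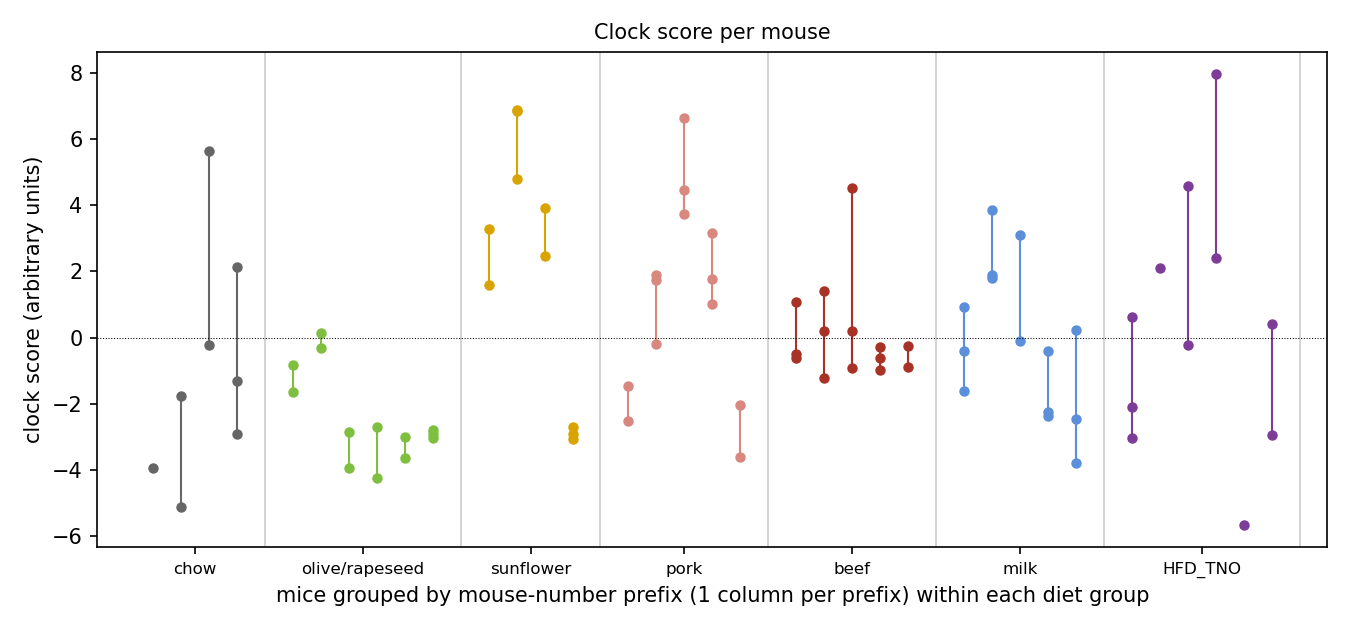
Clock score in arbitrary units of each of the 83 mice by mouse-number prefix and diet group. Prefix means on olive and rapeseed oil run from -3.49 to -0.10, and on sunflower oil from -2.89 to 6.18.

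Among the animal fats, no gene passed between beef and pork, milk and pork or milk and beef with edgeR, and 668, 1130 and 514 genes had an unadjusted p under 0.05. DESeq2 called 0, 48 and 0, and of the 48 between milk and pork fat 5 were higher and 43 lower on milk fat. Between milk and pork fat Scd1 was at 0.61, SE 0.19, adjusted p = 0.379, Apoa4 at 0.78, SE 0.23, adjusted p = 0.316 and Cidec at 0.63, SE 0.23, adjusted p = 0.471. DESeq2 called Scd1 (0.62, adjusted p = 0.0259) and Apoa4 (0.79, adjusted p = 0.0214). Between milk and pork fat, of the 14 cholangiocyte genes, none passed over all genes, and 6 were higher adjusted over the list alone. As a list they had a median log2 fold change of 0.64 (camera adjusted p = 1e-07, but adjusted p = 0.1 with an estimated correlation). In simulated data with known changes, 70%, 68% and 68% of genes changed 1.5-fold were found in these comparisons, and 88%, 90% and 94% of those changed 2-fold. The simulated mice were independent, and the 200 changed genes averaged above 1 CPM. Mice of a prefix can be alike in the data, so these rates may be too high for them. Between single plant oils and animal fats, 560 genes passed for pork, 2140 for beef and 2236 for milk fat against olive and rapeseed oil. Against sunflower oil 73 passed for beef and 134 for milk fat, and for pork fat Adam11 alone (1.33, SE 0.23, adjusted p = 0.00188), a gene named here after its values were seen. Adam11 lost that call with the prefix sums and with voom, which called 0 genes each (638 and 994 at an unadjusted p under 0.05), while DESeq2 called 3. With the cell-marker score edgeR called 10, 0 and 1 genes for pork, beef and milk fat against olive and rapeseed oil (1074 at an unadjusted p under 0.05 for beef), and 15 and 5 for beef and milk fat against sunflower oil. DESeq2 called 2410 for beef fat against olive and rapeseed oil. Prefix sums left 8, 995 and 1497 genes for pork, beef and milk fat against olive and rapeseed oil, and 1 and 2 for beef and milk fat against sunflower oil.

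HFD_TNO was compared with the mean of the 5 fats. A drug-metabolising gene was lower in HFD_TNO. Cyp3a11, a cytochrome P450 (chromosome 5, 145854426 to 145879964), averaged 1081 ± 282 CPM (n = 11) against 3278 ± 806 on milk fat (n = 14) and 3725 ± 1044 on chow (n = 8), a log2 fold change of -1.84 (SE 0.13, adjusted p = 4.17e-19). Cyp2c55 (-1.99, SE 0.21) and Cyp3a59 (-1.58, SE 0.21) were lower too, though reads of Cyp3a11 and Cyp3a59 are hard to tell apart. Of the 30 xenobiotic metabolism genes, 2 were higher and 4 lower over all genes, and 2 were higher and 9 lower adjusted over the list alone. Their median log2 fold change was -0.18 (camera adjusted p = 1.37e-09, and adjusted p = 0.0182 with an estimated correlation). Slco1a1 (2.94, SE 0.44) and Hsd3b5 (3.26, SE 0.57) were higher among 24 male-biased genes. Of these, 11 were higher over all genes, and 16 were higher and 1 lower adjusted over the list alone. Camera gave an adjusted p = 7.5e-14 at a median log2 fold change of 0.68, but adjusted p = 0.126 with an estimated correlation. The lipogenic genes Thrsp (-0.94, SE 0.19) and Fasn (-0.58, SE 0.15) and the droplet gene Cidea (-1.47, SE 0.38) were lower. Hsd3b5 and Cidea lost their calls with voom at 2.53 and -1.79 (adjusted p = 0.101 and 0.105). In HFD_TNO livers Hsd3b5 was at 4.282, 4.015 and 3.741 log2 CPM in replicates 6, 11 and 8. It ran from -3.07 to 1.315 in the others, so its rise was uneven. Replicates 6 and 8 share a mouse-number prefix, while replicate 11 shares one with replicate 10, which was at -2.299. The cell-marker score averaged 0.01 ± 1.08 in HFD_TNO. In all 188 genes passed, 95 higher and 93 lower. With no filter on low counts 923 passed, 764 higher and 159 lower. The male-biased members higher were 6 with counts summed over prefixes, 7 without the 5 libraries that stand apart and 3 with voom.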

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

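Chosen only after the results were seen were the tests of cell makeup, scaling, single libraries, the clock score and Y chromosome genes, and the regrouping counts for the 5 fats and for olive and rapeseed oil against chow. The other regrouping counts and the Xist test were set before their results were seen.

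Sterol synthesis and fatty acid oxidation genes were lower with animal fats than with plant oils, while the hepatocyte markers were lower too. Taking the mean log2 CPM of the hepatocyte markers away from that of the sterol list, in means per mouse-number prefix (15 against 10 prefixes), left a difference of -0.36 (SE 0.09, 2-sided permutation p = 0.00046), which argues against a lower hepatocyte share as the whole cause. A factor per library cancels in this difference, so it argues against scaling too. The 5 libraries that stand apart, left out together, were not the source, since 24 sterol genes were lower without them. For the fatty acid oxidation list the same difference was -0.01 (SE 0.06, permutation p = 0.877), so its fall may come from a lower share of hepatocytes in these samples. An effect of the fats on sterol synthesis within hepatocytes stays open as a hypothesis.

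Male-biased genes were lower on the 5 high-fat diets than on chow. In means per prefix, the mean log2 CPM of the list minus that of the hepatocyte markers differed by -2.39 (SE 0.09, 25 against 4 prefixes, 2-sided exact p = 4.21e-05, the smallest that 23751 regroupings allow). That argues against hepatocyte share as the whole cause. The difference is another measure than the median log2 fold change of the list, which was also -2.39. A whole library from a female mouse was argued against by Ddx3y, a gene of the Y chromosome, whose lowest level was 0.61 of the median. Xist, expressed from the inactive X chromosome, reached 1.78 CPM at most, above the bound of 1 CPM set in advance. Female tissue dilutes genes of the Y chromosome at least as much as male-biased genes. On the 5 fats 4 Y genes had a median log2 fold change of -0.26, from -0.33 (SE 0.10, Ddx3y) to -0.17 (SE 0.10, Kdm5d), against -2.39 for the male-biased list. This argues against an admixture of female tissue as the whole cause, while a trace of it is not ruled out. A loss of male-type liver expression on high-fat diets is a hypothesis that these data may fit, and the design gives no measure of hormones to test it.

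The 46 genes called between sunflower and olive and rapeseed oil lie beside a difference in clock score and in the cell-marker score, which averaged 0.25 ± 0.46 on sunflower oil (n = 10) and -0.63 ± 0.95 on olive and rapeseed oil (n = 13). With the clock score as a covariate the median absolute log2 fold change of the 45 called genes outside the clock list went from 0.63 (median SE 0.14) to 0.38 (median SE 0.15), a ratio of 0.61 (95% bootstrap interval 0.53 to 0.75 over 10000 draws). The calls ended because the folds shrank while their errors did not, although 45 of 45 kept their sign and 42 an unadjusted p under 0.05. With the cell-marker score edgeR called 0 genes as well (1142 at an unadjusted p under 0.05). The median absolute log2 fold change of the 45 called genes outside its lists went from 0.64 (median SE 0.14) to 0.49 (median SE 0.14), a ratio of 0.77 (95% bootstrap interval 0.7 to 0.94), and 45 kept an unadjusted p under 0.05. The makeup of the tissue and the time at which mice were killed could thus each account for part or all of these differences. The remaining ratios cannot decide this, since the genes were chosen as called in these data and each score is an incomplete measure. The bootstrap drew genes, not mice or prefixes. The library of sunflower replicate 8 was not the source, as 39 of the 46 stayed called without it.

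Other groupings of the same mice were tested with fits of the compared libraries alone, so that real counts differ from those of the 7-group model. The splits regroup single mice, so they test chance among mice and not among mouse-number prefixes. No correction over the 19 comparisons was made. Chance among mice is argued against where 1 of 50 or 1 of 100 splits, the real one, gave as many genes. That held for the 5 fats against chow (6776 against 1334 in the highest other split), olive and rapeseed oil (3053 against 4), sunflower oil (3842 against 1358), pork fat (5481 against 0), beef fat (6373 against 0), milk fat (6225 against 3798) and HFD_TNO against chow (3870 against 0). It also held for animal against plant fat (2985 against 12), sunflower against olive and rapeseed oil (13 against 7) and HFD_TNO against the 5 fats (156 against 15). For sunflower against olive and rapeseed oil this does not cover the 46 genes of the 7-group model. A fit of these groups alone shared 8 of its 13 calls with them. Against olive and rapeseed oil the counts were 374 against 1 for pork, 2335 against 3 for beef and 2090 against 740 for milk fat. Against sunflower oil they were 495 against 7 for beef and 412 against 1 for milk fat. Each of these also argues against chance among mice. For pork fat against sunflower oil 3 of 100 splits gave its 1 gene or more, with 4 in the highest. With no correction over the comparisons, that does not exclude chance among mice. Differences between prefixes are not excluded for sunflower against olive and rapeseed oil or for pork fat against sunflower oil. There edgeR on prefix sums called 0 and 0 genes (1369 and 638 at an unadjusted p under 0.05), and voom with the prefix as a random block 1 and 0. The prefix sums also left few calls for pork fat against olive and rapeseed oil (8) and for beef and milk fat against sunflower oil (1 and 2). For beef against pork, milk against pork and milk against beef, with 0 genes each by edgeR (668, 1130 and 514 at an unadjusted p under 0.05 in the 7-group model, and 0, 48 and 0 by DESeq2), 100 of 100 splits gave at least as many, as they must for a real count of 0, and the highest others were 10, 21 and 26, so the splits decide nothing there.

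Single mice lay far from the rest of their group for 15 of 226 pairs of a named gene with chow or sunflower oil, where chance gives about 11. The values are the gap to the nearest mouse as a share of the group's range. Among chow mice they were 0.549 for Cyp2b9 and 0.761 for Hao2 (both replicate 3, highest), 0.697 for Ifi44 (replicate 5, lowest), 0.583 for Cyp2c70 (replicate 5, highest) and 0.54 for Fgf21 (replicate 8, lowest). Pck1 had 0.542 (replicate 7, highest), Sprr1a 1 (replicate 4, the highest above mice at the floor) and Gpx3 0.596 (replicate 6, lowest). On sunflower oil the lowest mouse gave 0.524 for Cyp2b13 and 0.501 for Thrsp (replicate 6), 0.655 for Lox (replicate 1), 0.494 for Nsdhl and 0.505 for Dhrs9 (replicate 8), 0.576 for Slc10a1 (replicate 3) and 0.479 for Cyp3a59 (replicate 4).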

How the results depend on the processing

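The fits with a cell-marker or clock score and those without the 5 libraries that stand apart or without single mice were chosen only after the data were seen, and the others were planned. Of 139 results for named genes, 139 kept direction and side of the threshold with RLE size factors, 136 without a filter, 137 with R as a covariate and 134 with DESeq2. With the compared groups alone 129 of 138 did, with prefix sums 119, without libraries coded R 125, without the libraries that stand apart 127, with voom 119, with the clock score 125 and with the cell-marker score 56. The last setting lost the call of 75 and turned the direction of 8. The score is built from matrix, macrophage, endothelial and hepatocyte lists, so the losses of genes on those lists follow from how it is made, and chow livers lie apart from the others on it. Without sunflower replicate 8 alone, 60 genes passed for sunflower against olive and rapeseed oil in place of 46. No paired analysis was possible because replicate numbers only name mice, and each mouse-number prefix lies within 1 diet. Depth was at least 8519142 gene reads per library. In simulated data for milk against pork fat, with independent mice, 90% of genes changed 2-fold and 68% of those changed 1.5-fold were found.

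Counts that moved by over 1.5 times follow, and the cause was not tested unless the setting itself leaves out mice or adds genes. With the cell-marker score the counts against chow were 960 for the 5 fats, 1333 for olive and rapeseed oil, 899 for sunflower oil, 807 for pork, 634 for beef, 476 for milk fat and 706 for HFD_TNO. Animal against plant fat had 39. Against olive and rapeseed oil there were 0 genes for sunflower oil (1142 at an unadjusted p under 0.05 by edgeR), 10 for pork, 0 for beef and 1 for milk fat, and against sunflower oil 15 for beef and 5 for milk fat. With prefix sums there were 1481 for animal against plant fat, and against olive and rapeseed oil 0 for sunflower oil, 8 for pork and 995 for beef fat. Against sunflower oil they gave 0 for pork, 1 for beef and 2 for milk fat.

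Without a filter on low counts, the counts were 231 for sunflower and 1027 for pork fat against olive and rapeseed oil, 27, 116 and 375 for pork, beef and milk fat against sunflower oil, and 923 for HFD_TNO against the 5 fats. Fits of the compared groups alone gave 13 for sunflower against olive and rapeseed oil, and 495 and 412 for beef and milk fat against sunflower oil. Leaving out libraries coded R gave 2 and 369 for sunflower oil and pork fat against olive and rapeseed oil and 23 for beef fat against sunflower oil, and R as a covariate gave 230 for milk fat against sunflower oil. Without the libraries that stand apart, 22 and 224 genes passed for beef and milk fat against sunflower oil. With voom there were 1 for sunflower against olive and rapeseed oil, and 0 and 44 for pork and beef fat against sunflower oil. DESeq2 called 112 for sunflower against olive and rapeseed oil, 3, 177 and 362 for pork, beef and milk fat against sunflower oil, and 48 for milk against pork fat. The clock score gave 0 and 163 for sunflower oil and pork fat against olive and rapeseed oil, and 164 for beef fat against sunflower oil. Of 100 list tests past the threshold in 7 comparisons (those of the 5 fats with chow, animal with plant fats, the pairs within plant or animal fats, and HFD_TNO with the 5 fats), 13 passed with an estimated correlation.

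For the 5 fats against chow, the cell-marker score turned the log2 fold change of Lox to -0.58, Col1a1 to 0.00, Elovl3 to 0.15, Saa1 to 0.17, Spp1 to -0.74 and Ldlr to 0.36. Voom turned Saa1 to 0.38, and with prefix sums Saa1 lost its call (-0.94, adjusted p = 0.14). For animal against plant fat, the score turned Gpnmb to -0.04 and Hal to 0.02.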

Other observations

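The tests of prefixes against the clock score and of animal against plant fat along the change from chow were chosen only after the results were seen, and the gene lists were fixed beforehand. On the 5 fats against chow, the gluconeogenic enzyme gene Pck1 (-1.62, SE 0.14) and the insulin-repressed gene Igfbp1 (-1.59, SE 0.24) fell, and among glucose metabolism genes 6 of 25 were higher and 9 lower (the same counts adjusted over the list alone, camera adjusted p = 0.209). Both lost their calls with the cell-marker score (Pck1 -0.69, adjusted p = 0.104; Igfbp1 -1.15, adjusted p = 0.15). The iron hormone gene Hamp (-2.07, SE 0.23) and Saa1 (-1.04, SE 0.36, adjusted p = 0.0152) fell and Lcn2 rose (1.85, SE 0.39) among acute phase genes, of which 6 of 25 were higher and 11 lower (6 and 12 adjusted over the list alone, camera adjusted p = 0.687). Saa1 lost its call with prefix sums (-0.94, adjusted p = 0.14) and turned direction with voom and the prefix block (0.38) and with the cell-marker score (0.17), so its fall is uncertain. With that score Hamp (-0.37, adjusted p = 0.754) and Lcn2 (0.18, adjusted p = 0.931) lost their calls. Saa1 shares reads with a close copy. The lymphatic and sinusoidal marker Lyve1 rose (1.63, SE 0.22), and among endothelial genes 13 of 18 were higher and 2 lower (14 and 2 adjusted over the list alone, camera adjusted p = 0.000571, but adjusted p = 0.0871 with an estimated correlation). Osteopontin, Spp1, rose (2.33, SE 0.31), and among cholangiocyte genes 9 of 14 were higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.00312, but adjusted p = 0.258 with an estimated correlation). Spp1 turned direction with the score (-0.74, adjusted p = 0.0757). The retinoic acid hydroxylase Cyp26a1 was at -2.13, SE 0.21, adjusted p = 6.13e-14 and the retinol acyltransferase Lrat at 0.86, SE 0.13, adjusted p = 1.53e-08, and among retinoid genes 9 of 26 were higher and 8 lower (10 and 8 adjusted over the list alone, camera adjusted p = 0.638). Lrat lost its call with the score (0.04, adjusted p = 0.961). The vitamin mix of the milk fat diet held 50% less vitamin A, and the vitamin A of chow is not recorded here. Diet fat and vitamin A are thus not separated for the retinoid genes. The clock genes Bhlhe41 (-1.90, SE 0.26) and Noct (-1.28, SE 0.24) fell, and among clock genes 2 of 20 were higher and 11 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0341, but adjusted p = 0.258 with an estimated correlation). Under the score Bhlhe41 (-0.69, adjusted p = 0.566) and Noct (-0.53, adjusted p = 0.674) lost their calls. Among desaturases and elongases Scd2 rose (1.67, SE 0.19) and Elovl3 fell (-2.32, SE 0.29), and of the whole list 5 of 16 were higher and 4 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.342). The score took the call of Scd2 (0.18, adjusted p = 0.73) and turned Elovl3 (0.15, adjusted p = 0.939).

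For the remaining lists on the 5 fats against chow, among bile acid and sterol transporters 5 of 17 were higher and 7 lower (5 and 8 adjusted over the list alone, camera adjusted p = 0.638), with a median of 0.04 and a mean of -0.21. Among lipoprotein genes 8 of 29 were higher and 13 lower (8 and 14 adjusted over the list alone, camera adjusted p = 0.259), with a median of -0.14 and a mean of 0.10. Among xenobiotic genes 8 of 30 were higher and 11 lower (8 and 13 adjusted over the list alone, camera adjusted p = 0.773), with a median of -0.23 and a mean of 0.58. Among LXR targets 7 of 13 were higher and 4 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0264, but adjusted p = 0.0871 with an estimated correlation), and among NRF2 and oxidative stress genes 14 of 28 were higher and 8 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0144, but adjusted p = 0.083 with an estimated correlation). Among ER and integrated stress genes 6 of 27 were higher and 7 lower (the same counts adjusted over the list alone, camera adjusted p = 0.908), with a median of -0.06 and a mean of 0.07. Among respiratory chain genes 0 of 31 were higher and 10 lower (the same counts adjusted over the list alone, camera adjusted p = 0.021, but adjusted p = 0.634 with an estimated correlation), and among neutrophil genes 1 of 11 was higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.451). For genes of other tissues, among adipocyte genes 1 of 3 was higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.697), among pancreas genes 0 of 2 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.491) and among blood and muscle genes 1 of 9 was higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.908). With animal against plant fats the sulfotransferase Sult1e1 (3.48, SE 0.55, adjusted p = 6.83e-06), the oxidase subunit Cybb (0.60, SE 0.12) and the peroxidase Gpx3 (0.71, SE 0.11) rose. The retinol dehydrogenase Rdh11 (-0.54, SE 0.11) and the retinol carrier Rbp4 (-0.28, SE 0.06) fell, among retinoid genes of which 2 were higher and 6 lower (2 and 7 adjusted over the list alone). Camera had adjusted p = 0.0328 there, but adjusted p = 0.178 with an estimated correlation, at a median of -0.06 and a mean of 0.02. Milk fat, 1 of the animal fats, came with 50% less vitamin A in the vitamin mix. The part of vitamin A in these retinoid changes was not tested. Cybb (0.15, adjusted p = 0.669), Rdh11 (-0.33, adjusted p = 0.284) and Rbp4 (-0.05, adjusted p = 0.781) lost their calls with the cell-marker score.

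A hypothesis for the clock score is that mice with the same prefix were killed at about the same time. Of the variation of the score within diets, 76.4% lay between prefixes, against 36.8% by degrees of freedom alone. A permutation test with 100000 shuffles of scores within diets gave p = 1e-05, the smallest they can give. For the cell-marker score the same test gave permutation p = 0.127. This may reflect time of day or another property that mice of a prefix share, since the labels give no time.

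A further hypothesis is that animal fats carry the liver further along the change from chow to high-fat feeding. Of the 1843 genes called both for the 5 fats against chow and for animal against plant fat, 96.5% had the same sign, with 989 higher and 790 lower in both. Independent lists would share 281 and 241. Over all genes, called or not, 69.6% had the same sign, against 48.8% in simulated unchanged groups. Both comparisons use the same high-fat libraries, and the animal fats (pork, beef and milk) are among the 5 fats. A gene changed by animal fats alone would thus have the same sign in both. Simulated unchanged groups and independent lists hold no such genes, so the agreement cannot tell the hypothesis from effects of animal fats alone. Across genes, which are not independent replicates, the correlation of log2 fold changes was 0.47 against -0.035 in simulated unchanged groups, and the covariance was 0.1288 against -0.00219. The cell-marker score rises along the same order of diets, so the shared direction may lie in the makeup of the tissue. Going the other way were 64 genes, of which 51 were higher on the 5 fats than on chow and lower with animal than with plant fats. Of those 64, 13 were on the PPARalpha and fatty acid oxidation list, which had 21 genes called in both comparisons.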
